A study of Mus musculus with 16 samples.

How the data were processed

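Polyadenylated RNA was sequenced from the livers of 16 mice in 4 groups of 4. The groups were wild-type C57BL/6 Ntac mice given vehicle or TCPOBOP and mice humanized for PXR, CAR and CYP3A4/3A7 given vehicle or TCPOBOP. Per the labels, the vehicle was 2% DMSO in corn oil, the dose was 3 mg/kg in 2 administrations 24 h apart, and the treatment lasted 48 h. Sex, age, time of day, feeding, litter and sequencing batch are not given in the sources used here. The labels name Trizol extraction, poly(A) selection, a NEBNext library kit, the STAR aligner, DESeq2 and the mm10 genome. Versions, the counting program, the annotation release, strandedness and the handling of reads that map to several places are not given in the sources used here.

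The deposited table holds counts, as whole numbers for 40458 RefSeq transcript accessions in 16 libraries. The values were checked to be whole numbers whose totals over all accessions differed between libraries, from 11827994 to 37998473 counts. Among counts of 20 or more, 74.9% were even, against the 75% that halved counts rounded to even numbers would give. The values, used as given, may thus be halved counts, so floors and intervals that assume single reads are approximate. Accessions were joined to mouse gene symbols for 40219 entries through the RefSeq table and for 125 more through the GENCODE table. The remaining 114 accessions, which held 0.227 to 0.582% of the counts of a library, were each kept as a gene of their own. Isoforms of a gene carried nearly the same count, with a median ratio of 0.978 between a further isoform and the highest. Each gene was therefore represented by its accession with the highest mean count, which gave 24970 genes, 7618 of them with more than 1 accession. Members of closely related families, such as Mup, Cyp3a, Cyp2c, Gsta, Gstm, Sult and Hba genes, share sequence, so the value of a single member is less certain than that of the family. The human PXR, CAR and CYP3A genes are not part of the mouse transcript table and were not analysed here.

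All 16 libraries were fitted together in edgeR 4.0.16 (limma 3.58.1, R 4.3.3). The fit used a mean for each of the 4 groups, filterByExpr, TMM normalization and quasi-likelihood F tests, and it kept 12913 genes. It had 12 residual degrees of freedom and a common biological coefficient of variation of 0.259. The tests were two-sided, and every adjusted p of a gene is a Benjamini-Hochberg value of this edgeR test within its comparison, with 0.05 as the threshold. The 4 comparisons were TCPOBOP against vehicle in each strain, the difference between these effects, called the interaction, and humanized against wild-type mice under vehicle. Expression is given in TMM-scaled CPM, that is, counts scaled by the gene-level total of each library, as mean ± SD with n = 4 mice per group, and log2 changes are given ± SE. A group whose libraries all held 0 counts was set to a floor of 3 counts over the group. A group with 1 to 3 counts is given as a ratio with its 95% counting interval. These intervals and floors cover at most counting error.

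Data were simulated with the same library sizes and, for each gene, a spread shared by all groups. In these data, a 2-fold change was recovered for 49.3% of changed genes in the wild-type comparison and 51.5% in the humanized comparison. For the interaction, a 2-fold difference was recovered for 21.1% and a 4-fold difference for 76.7% of changed genes. Between 3% and 4.8% of the calls were false. Genes were drawn independently, without libraries that stood apart and without trends with transcript length or GC content. Recovery and false calls in the real data may therefore differ.

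The 30 gene lists, the 4 comparisons and the rule for named genes were written before the data were examined. The lists hold textbook members of hepatic pathways, of zonation, sex-biased and clock genes, and of markers for cell types. Each list with at least 3 tested members, 29 in all, was tested with camera, a competitive test of a list against all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. It was repeated with a correlation estimated for each list. The numbers of members that rose and fell are given over all genes tested and adjusted over the list alone. The lists overlap in a few members, such as Nqo1, Cyp1a2 and Pck1.

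The rule for named genes had 3 parts. It took the 10 largest changes in each direction among called genes of at least 5 CPM without overlap between the compared groups, where the interaction needed no such gap. It also took up to 4 called members of each list with the smallest p, and a fixed set that included Nr1i3, Nr1i2, Cyp2b10, Cyp3a11, Cyp7a1, Ppara, Fasn, Mki67 and Ccnd1. Predicted genes, pseudogenes and accessions with no symbol were left out of the first part. Of the genes this rule called, 76 of 89 in wild-type liver, 20 of 57 in humanized liver, 66 of 80 in the interaction and 60 of 100 between strains kept the call when any 1 of the 16 libraries was left out. The text prints mainly those, a choice made after their values were seen. Some genes that the rule named are not reported here. Moves of a count of list members without 1 library are mostly not given where both counts were under 4, and lists that did not pass in the interaction or between strains are given only in part.

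The overlap of calls was tested with a one-sided Fisher's exact test on the 12913 genes. Alternatives chosen before the data were examined were DESeq2 size factors, no filter on low counts, a stricter filter of 1 CPM in 4 libraries, the replicate number as a block, the DESeq2 1.42.0 Wald test, a fit of the compared groups alone, a 2-fold minimum, and leaving out each library in turn. A further 5 alternatives were chosen after seeing the data. They were the sum of all isoforms of a gene, all libraries thinned to 6831626 gene-level counts, 2 libraries that stood apart left out together, and the trend of each library with transcript length, or with length and GC content, removed through offsets.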

Results

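Liver messenger RNA was measured in 16 mice to ask how TCPOBOP, a synthetic agonist of the mouse constitutive androstane receptor (CAR), acts in mice humanized for PXR, CAR and CYP3A4/3A7. Each strain, wild-type and humanized, had 4 vehicle and 4 TCPOBOP mice. Total counts per library were 11827994 to 19483951 in wild-type vehicle, 30228724 to 37998473 in wild-type TCPOBOP, 12612610 to 16904182 in humanized vehicle and 14019983 to 16755802 in humanized TCPOBOP mice. The greater depth thus coincided with 1 group. A count of 3 corresponded to 0.134 to 0.439 CPM. The first principal component of the 1000 most variable genes held 53.5% of their variance.

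Mouse Nr1i3, Nr1i2 and several mouse Cyp3a genes were low in humanized livers. Nr1i3, which encodes CAR (NM_001243063, mm10 chromosome 1, 171213934 to 171218845), was at 100.3 ± 7.32 CPM in wild-type vehicle and 2.20 ± 0.49 CPM in humanized vehicle livers (SD, n = 4). It was 45.1-fold lower, a log2 difference of -5.50 ± 0.24 (adjusted p = 1.21e-10). Nr1i2, which encodes PXR (NM_010936, chromosome 16, 38248349 to 38294849), was at 136.5 ± 39.8 and 19.0 ± 1.25 CPM, a difference of -2.85 (adjusted p = 1.65e-07). Cyp3a11 (NM_007818, chromosome 5, 145854607 to 145879854) fell from 2984 ± 1960 CPM to 0.56 ± 0.35 CPM, with 1 to 8 counts per humanized vehicle library. Cyp3a25 fell from 711 ± 375 to 0.209 ± 0.191 CPM and Cyp3a59 from 72.9 to 1.79 CPM. Cyp3a44 had no count in any of the 8 humanized libraries and was at least 7.77-fold lower against a floor of 3 counts over the humanized vehicle group. Cyp3a57, with 1 count in the wild-type vehicle group, was 222-fold higher in humanized vehicle livers (39.8 to 8760). Whether reads of the human genes were counted for Cyp3a57, Nr1i2 or other related mouse genes was not tested. Cyp3a13 was not past the threshold (0.69, adjusted p = 0.0716; 3 of 4 libraries above all wild-type vehicle libraries). TCPOBOP lowered Nr1i3 in wild-type liver to 52.3 ± 4.83 CPM (-0.94, adjusted p = 0.00198, 4 of 4 libraries below all vehicle libraries). Nr1i3 did not pass in humanized liver (0.66, adjusted p = 0.152, 3 of 4), and Nr1i2 passed in neither strain (-0.21, adjusted p = 0.554, and -0.05, adjusted p = 0.931).

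**Figure D1:**
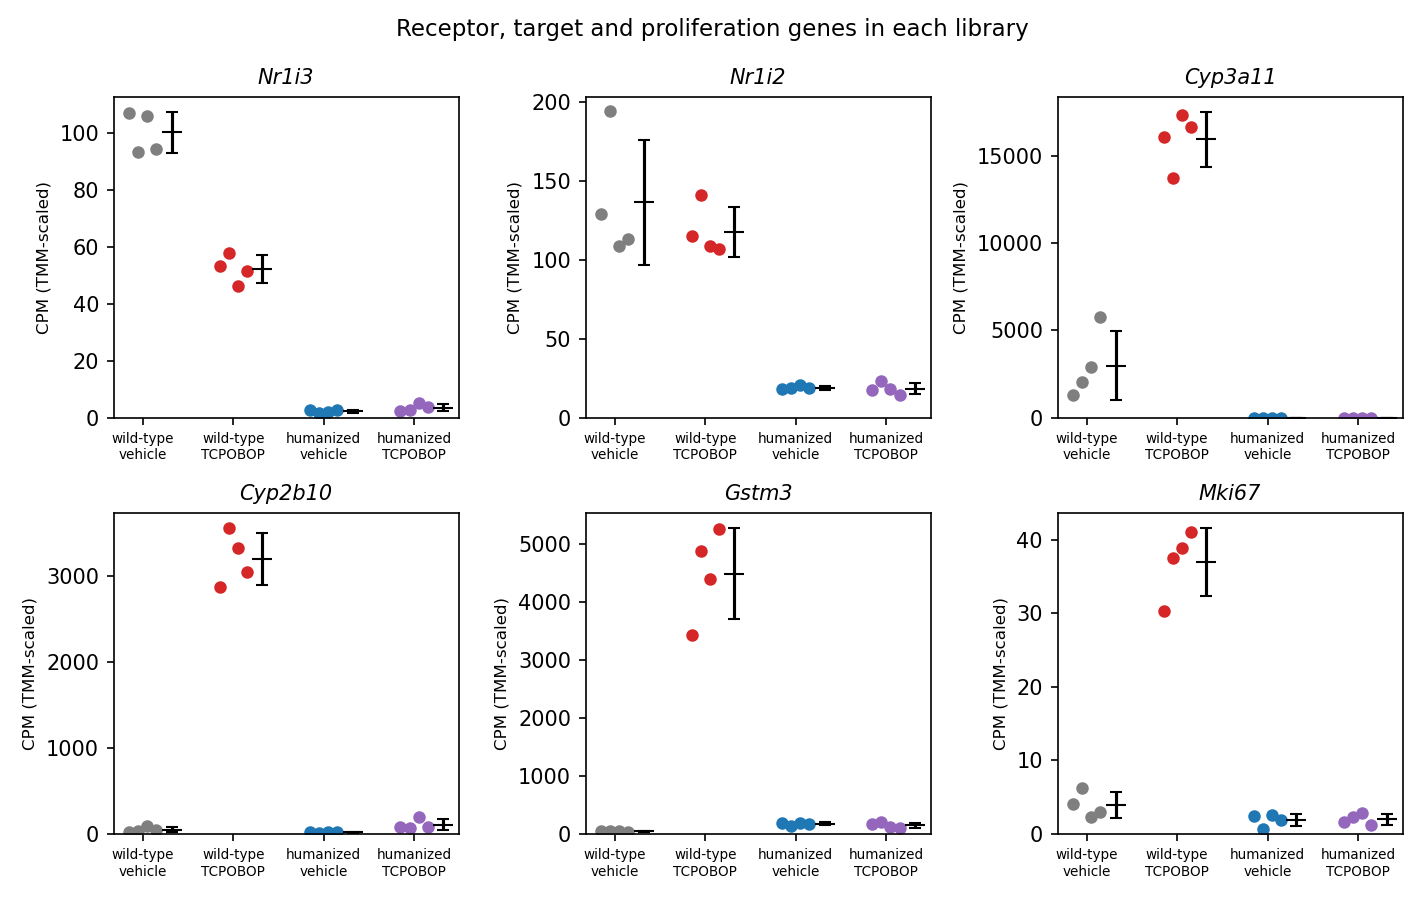
TMM-scaled CPM (vertical axes) of 6 genes in each library of the 4 groups (points), with mean and SD (bars, n = 4 mice). Nr1i3 lies between 93.4 and 107 CPM in wild-type vehicle livers and between 1.63 and 2.7 CPM in humanized vehicle livers.

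The comparison of TCPOBOP with vehicle in wild-type mice asked which liver genes the compound changes where its receptor is mouse CAR. TCPOBOP raised drug-metabolism genes and 35 of 37 cell-cycle genes, and lowered some genes of fatty acid oxidation (16 of 35), lipoprotein handling (11 of 28), glucose production (6 of 21) and the periportal zone (8 of 18). With an estimated correlation between genes, the fatty acid oxidation (adjusted p = 0.0927), glucose (adjusted p = 0.151) and periportal lists (adjusted p = 0.0937) did not pass. Cyp2b10, the classical CAR target, rose 66.2-fold. The proliferation gene Mki67 rose 9.46-fold and the gluconeogenic gene Pck1 fell 3.88-fold. Past the threshold were 1046 genes that rose and 645 that fell, 1691 in all, and 990 of them changed at least 2-fold. For each gene given below as changed, all 4 libraries of 1 group lay beyond all 4 of the other unless a smaller number is given.

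Phase I drug-metabolism genes rose in wild-type liver. Cyp2b10 (NM_009999, chromosome 7, 25897658 to 25926624) rose from 48.2 ± 30.9 to 3200.2 ± 305 CPM, by 6.05 ± 0.49 on the log2 scale (adjusted p = 2.43e-07). Cyp2c55 (NM_028089, chromosome 19, 39006940 to 39042690) rose from 18.9 ± 8.88 to 1321 ± 219 CPM, by 6.12 ± 0.35 (adjusted p = 6.22e-09). Of the 14 CAR targets of the CYP2 list, 10 rose and 1 fell, as they did adjusted over the list alone. The list had a median log2 change of 1.76 (camera adjusted p = 2.01e-15, and adjusted p = 0.000738 with an estimated correlation). Cyp2c29, Cyp2c37, Cyp2c50, Cyp2a5 and Cyp1a2 were among those that rose, and Cyp2c38 fell (-2.91, adjusted p = 1.34e-06). Of 7 mouse Cyp3a genes, 4 rose over all genes and adjusted over the list alone, with a median of 1.40 (camera adjusted p = 4.15e-05, and adjusted p = 0.0596 with an estimated correlation). They were Cyp3a11, which rose 5.34-fold to 15945 ± 1583 CPM (2.42, adjusted p = 0.000259), Cyp3a13 (1.08), Cyp3a16 (3.27) and Cyp3a44 (3.11). Of 5 targets of the aryl hydrocarbon receptor, 4 rose by either adjustment, which were Cyp1a1, Cyp1a2, Nqo1 and Ugt1a6a (median 1.47, camera adjusted p = 8.7e-06, and adjusted p = 0.00743 with an estimated correlation). Cyp1a2, which metabolizes caffeine and aromatic amines, rose 4.15-fold (2.05, adjusted p = 2.61e-06).

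Conjugation and efflux genes, and some antioxidant genes, rose with them. Of 38 conjugation and efflux genes, 31 rose and 7 did not pass, against 32 that rose and 1 that fell adjusted over the list alone. Their median log2 change was 1.58 (camera adjusted p = 8.95e-53, and adjusted p = 6.28e-05 with an estimated correlation). The glutathione transferase gene Gstm3 (NM_010359, chromosome 3, 107963696 to 107969174) rose 104-fold, from 42.9 ± 10.4 to 4485 ± 787 CPM (6.71 ± 0.30, adjusted p = 2.06e-10). Gsta1 rose by 8.83 on the log2 scale (adjusted p = 8.26e-09), the carboxylesterase gene Ces2a rose 10.6-fold and the efflux pump gene Abcc4 rose 8.28-fold. The estrogen sulfotransferase gene Sult1e1 had 1 count in the vehicle group and rose 1620-fold (291 to 63900). Of 18 targets of the oxidative-stress factor NRF2, 8 rose (12 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 4.07e-11, and adjusted p = 0.0137 with an estimated correlation). Srxn1, which repairs oxidized peroxiredoxins, rose 6.5-fold (2.70, adjusted p = 2.5e-06). Outside the lists, Pnliprp1 had no count in vehicle livers and rose at least 279-fold against a floor of 3 counts over the group. Meig1 had 1 vehicle count and rose 519-fold (93.1 to 20500). Chrdl2 (6.48), Gprc5a (6.20) and Nebl (6.05) also rose, whereas the retinoid genes Cyp26b1 (-3.39), Rdh16 (-3.31) and Rdh9 (-3.28) fell.

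Proliferation genes rose in wild-type liver. Of 37 cell-cycle genes, 35 rose and Mcm10 fell, by either adjustment, with a median log2 change of 2.94 (camera adjusted p = 6.63e-52, and adjusted p = 0.00264 with an estimated correlation). Mki67 (NM_001081117, chromosome 7, 135689784 to 135716450) rose from 3.91 ± 1.74 to 37.0 ± 4.67 CPM (3.24 ± 0.33, adjusted p = 2.63e-06). Rrm2, which makes deoxynucleotides for replication, rose 16.2-fold, and the mitotic genes Prc1 (3.47) and Aurka (2.87) rose as well. Cyclin D1 (Ccnd1) rose by 1.34 (adjusted p = 0.0303, 3 of 4 libraries above all vehicle libraries). Its adjusted p was 0.086, 0.0949 and 0.0824 without wild-type vehicle replicates 1, 3 and 4, and 0.0512, 0.0751 and 0.0846 without wild-type TCPOBOP replicates 2, 3 and 4. Of 14 growth-arrest and p53 genes, Gadd45a, Myc (3 of 4 libraries) and Eda2r rose and 1 fell (3 and 2 adjusted over the list alone). That list had a camera adjusted p = 0.0253 (adjusted p = 0.101 with an estimated correlation), which was 0.0503 without wild-type vehicle replicate 1. Gadd45b did not pass (0.82, adjusted p = 0.133, 2 of 4).

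Some genes of lipid use and transport fell. Of 35 genes of fatty acid oxidation and PPAR alpha targets, 16 fell (23 adjusted over the list alone), with a median log2 change of -0.68 (camera adjusted p = 1.4e-10, and adjusted p = 0.0927 with an estimated correlation). Among them were Ppara itself (-1.21, adjusted p = 0.0112), the omega-hydroxylase gene Cyp4a10 (-5.40, and -3.81 without wild-type vehicle replicate 4, at 198 CPM against 9.76 to 30.2 CPM in the other 3) and Acot1 (-2.89). Of 28 lipoprotein and lipid transport genes, 11 fell and Mttp rose (14 and 1 adjusted over the list alone, median -0.69, camera adjusted p = 8.7e-06, and adjusted p = 0.0167 with an estimated correlation). The number that fell was 7 without wild-type vehicle replicate 3 and 3 or 4 without wild-type TCPOBOP replicates 3 or 4. The HDL receptor gene Scarb1 fell from 219 ± 31.3 to 93.4 ± 16.5 CPM (-1.23, adjusted p = 0.000612), and the sterol exporter gene Abcg5 fell by 1.22. Of 25 cholesterol synthesis genes, 4 rose by either adjustment, Fdps, Sqle and Tm7sf2 among them (median 0.42, camera adjusted p = 0.0108, and adjusted p = 0.545 with an estimated correlation). Their number was 2, 7 and 1 without wild-type vehicle replicates 1, 2 and 3, and 2 without wild-type TCPOBOP replicate 4. Without wild-type TCPOBOP replicate 2 it was 0 and the camera adjusted p was 0.075. Of 27 lipogenesis genes, 2 rose and 4 fell (3 and 5 adjusted over the list alone), with a median of 0.05, a mean of -0.07 and a camera adjusted p = 0.831 for a fall. The number that fell was 1 without wild-type TCPOBOP replicate 3 or 4. The desaturase gene Fads1 rose from 609.5 ± 25.0 to 1221 ± 142 CPM. Srebf1 (-0.71, adjusted p = 0.371), Pnpla3 (0.52, adjusted p = 0.795) and Fasn (0.60, adjusted p = 0.418) did not pass, with 0, 0 and 1 of 4 libraries beyond all vehicle libraries.

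Some glucose and bile acid genes changed in wild-type liver too. Of 21 gluconeogenesis and glucose-handling genes, 6 fell and Pygl rose (10 and 1 adjusted over the list alone, median -0.54, camera adjusted p = 0.000381, and adjusted p = 0.151 with an estimated correlation). The number that fell was 3 without wild-type TCPOBOP replicate 4. Pck1, the gene of the rate-limiting gluconeogenic enzyme (NM_011044, chromosome 2, 173153073 to 173159274), fell from 4458 ± 745 to 1149 ± 422 CPM (-1.96 ± 0.29, adjusted p = 0.000165). Fbp1 (-1.35) and the glucose transporter gene Slc2a2 (-1.53, adjusted p = 0.00336) also fell. Of 21 bile acid genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone), without a call for the list (median -0.28, camera adjusted p = 0.0563). The list passed without wild-type vehicle replicate 1 (0.0468) or 2 (0.00609), wild-type TCPOBOP replicate 1 (0.0402) or humanized vehicle replicate 1 (0.0496). The number that fell was 2 without wild-type vehicle replicate 3 or wild-type TCPOBOP replicates 3 or 4. Akr1d1, a bile acid synthesis gene, rose from 159 ± 27.1 to 533 ± 66.4 CPM, Klb (-1.91) and Cyp7b1 (-1.59) fell, and Cyp7a1 did not pass (0.02, adjusted p = 0.983, 1 of 4).

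Zonal, sex-biased and stress genes moved in part. Of 18 periportal genes, 8 fell (10 adjusted over the list alone), with a median log2 change of -0.87 (camera adjusted p = 4e-08, and adjusted p = 0.0937 with an estimated correlation), Etnppl (-2.83), Pigr (-1.70) and Hal (-1.40) among them. Of 18 pericentral genes, 5 rose and 5 fell (6 and 7 adjusted over the list alone, median -0.14, mean 0.03, camera adjusted p = 0.642 for a fall). The number that fell was 3 without wild-type vehicle replicate 1 or wild-type TCPOBOP replicates 3 or 4. Lect2 rose (1.87, adjusted p = 0.000254) and the glutamate transporter gene Slc1a2 fell (-1.68, adjusted p = 4.15e-05). Of 19 male-biased genes, 7 fell and Cyp4a12a rose by either adjustment (median -0.46, camera adjusted p = 0.0121, and adjusted p = 0.6 with an estimated correlation). That list did not pass without wild-type vehicle replicate 3 (0.0532) or 4 (0.0792). Of 15 female-biased genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone), with a median of -0.78, a mean of 0.21 and a camera adjusted p = 0.0813 for a rise. It was 0.00382 without wild-type vehicle replicate 2, where 6 rose and 3 fell. It was 0.0249 and 0.0207 without wild-type TCPOBOP replicates 3 and 4, with 3 that fell. Of 26 acute phase genes, Orm3 rose (2.35) and 5 fell, Mt2 (-2.51) and Itih3 (-1.49) among them (2 and 6 adjusted over the list alone, camera adjusted p = 0.0341, and adjusted p = 0.609 with an estimated correlation). It was 0.135, 0.0537, 0.0613 and 0.126 without wild-type vehicle replicates 1 and 2 and wild-type TCPOBOP replicates 2 and 4.

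Few other groups moved in wild-type liver. Of 20 genes of the unfolded protein response, 1 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.059). This list passed without humanized TCPOBOP replicates 1 (0.034) or 3 (0.0488) or wild-type TCPOBOP replicates 1 (0.0352) or 2 (0.0374). Of 20 interferon genes, Rsad2 rose by either adjustment (1.44, adjusted p = 0.00281, camera adjusted p = 0.201). Of 18 clock genes, Cry1 fell by either adjustment (-1.07, adjusted p = 0.00142, camera adjusted p = 0.119, and 0.0386 without wild-type vehicle replicate 3). In edgeR, 0 of 16 Kupffer cell markers changed, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 (camera adjusted p = 0.197, and 0.0302 without wild-type vehicle replicate 4). Of 3 neutrophil markers 0 changed, with 1 unadjusted and 0 by DESeq2 (camera adjusted p = 0.389). Of 16 sinusoidal endothelial markers 0 changed by edgeR, unadjusted or by DESeq2 (camera adjusted p = 0.197). Of 16 stellate cell markers 0 changed, with 2 unadjusted and 1 by DESeq2 (camera adjusted p = 0.201). For 9 cholangiocyte markers (camera adjusted p = 0.197) and 7 erythroid markers (0.154, and 0.0464 without wild-type TCPOBOP replicate 1) the number was 0 by edgeR, unadjusted and by DESeq2. Of 4 lymphocyte markers 1 fell by either adjustment (camera adjusted p = 0.201). Of 4 adipocyte markers Lipe fell (-0.86), and 1 rose and 1 fell adjusted over the list alone (median and mean 0.04, camera adjusted p = 0.831 for a fall). Of 2 pancreatic acinar markers, too few for camera, Cela1 fell by either adjustment (-1.34).

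**Figure D2:**
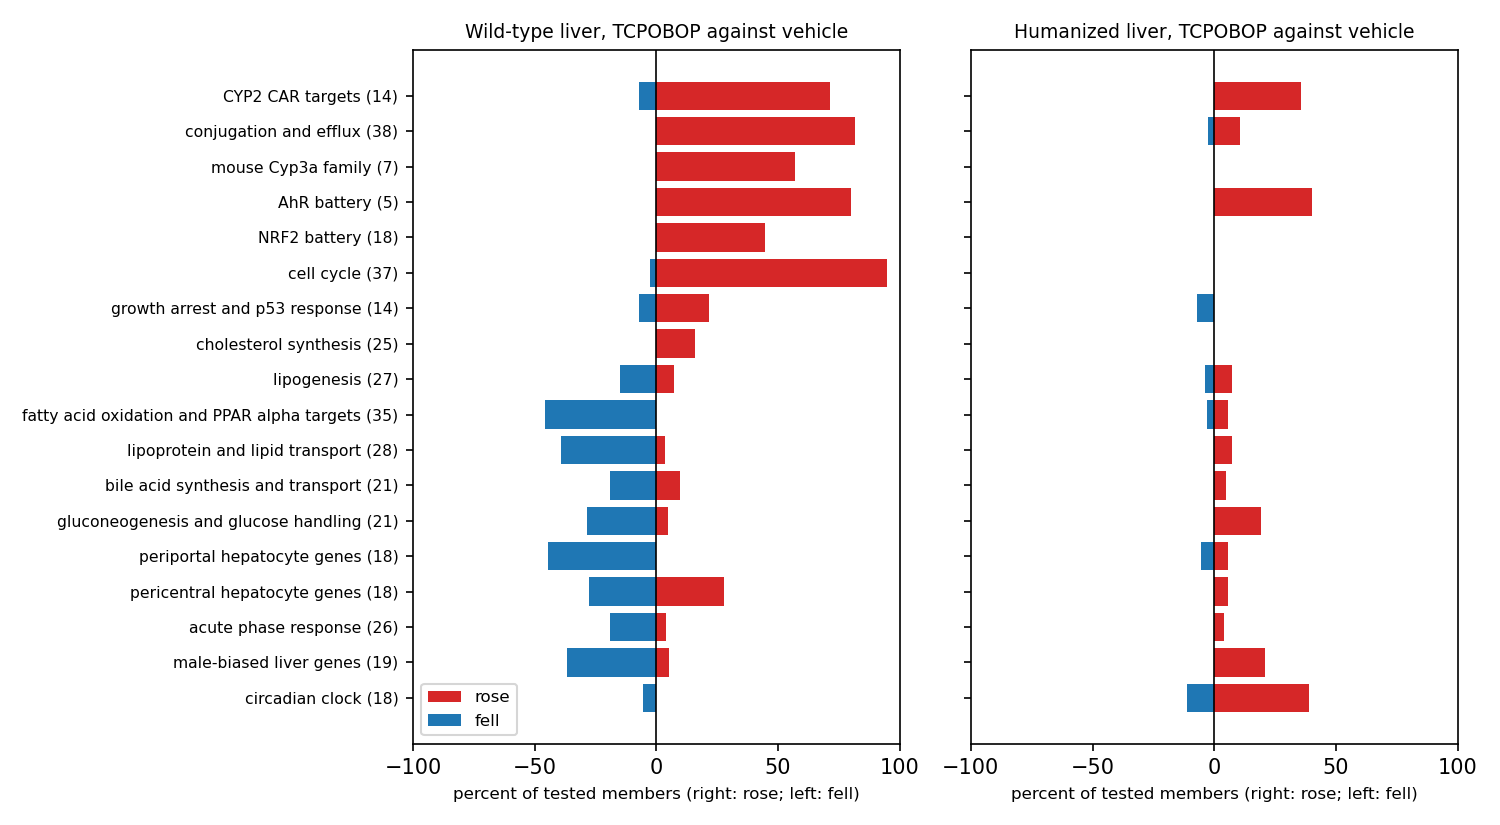
Percent of the tested members (horizontal axes) of 18 gene lists that rose (right) or fell (left) past the threshold with TCPOBOP in wild-type and humanized liver, with the number tested in parentheses. In the cell-cycle list, 35 of 37 members rose in wild-type liver.

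The wild-type comparison had 3239 genes at an unadjusted p under 0.05. The groups did not overlap for 2697 genes, which is 20.9% of those tested, where chance gives 2.86%. The number of calls was 1068 without wild-type TCPOBOP replicate 4.

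The comparison of TCPOBOP with vehicle in humanized mice asked what the compound changes in liver with human CAR and PXR. A few CAR targets rose, led by Cyp2b10, which rose 6.04-fold. Several of the largest changes were in clock and glucose-handling genes, such as Dbp and Slc2a2, that also differed between the strains under vehicle. Past the threshold were 171 genes that rose and 154 that fell, 325 in all, and 230 of them changed at least 2-fold.

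Drug-metabolism genes moved less than in wild-type liver. Of the 14 CAR targets of the CYP2 list, 5 rose (7 adjusted over the list alone), with a median log2 change of 0.75 (camera adjusted p = 2.25e-06, and adjusted p = 0.0492 with an estimated correlation). They were Cyp2b10, Cyp2c50, Cyp2c55, Cyp1a1 and Cyp1a2. Their number was 2 without humanized vehicle replicate 4. It was 3 without humanized vehicle replicates 1, 2 or 3, humanized TCPOBOP replicates 3 or 4, or wild-type TCPOBOP replicates 1, 3 or 4. Cyp2b10 rose from 17.4 ± 3.83 to 105 ± 64.4 CPM (2.59 ± 0.42, adjusted p = 0.00434), with replicate 3 at 201 CPM and the other TCPOBOP libraries at 63.3 to 79.7 CPM. Cyp1a2 rose 2.15-fold (1.10, adjusted p = 0.0086). Of 38 conjugation and efflux genes, 4 rose and 1 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.269). The number that rose was 1 without humanized vehicle replicates 1, 3 or 4, humanized TCPOBOP replicates 3 or 4 or wild-type TCPOBOP replicates 3 or 4. It was 2 without humanized vehicle replicate 2 or wild-type TCPOBOP replicate 1. Sult5a1, a sulfotransferase gene, rose from 7.31 ± 1.42 to 17.8 ± 3.87 CPM (1.29, adjusted p = 0.00434). Of 5 aryl hydrocarbon receptor targets, Cyp1a1 and Cyp1a2, which are also counted in the CYP2 list, rose (2 and 1 fell adjusted over the list alone, camera adjusted p = 0.0331, and adjusted p = 0.237 with an estimated correlation). That list did not pass without humanized vehicle replicate 3 (0.0573) or humanized TCPOBOP replicates 2 (0.0656) or 3 (0.0997).

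Cell-cycle, NRF2 and cholesterol synthesis genes did not pass in humanized liver. Of 37 cell-cycle genes, 0 passed in edgeR or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 1 by DESeq2 (median 0.12, camera adjusted p = 0.524). Mki67 was at 1.9 ± 0.852 and 1.98 ± 0.733 CPM (0.08, adjusted p = 0.949, 1 of 4), and Ccnd1 did not pass (-0.50, adjusted p = 0.575, 3 of 4). Of 7 Cyp3a genes, 0 passed by edgeR, unadjusted or by DESeq2 (camera adjusted p = 0.196), Cyp3a13 (-0.11, adjusted p = 0.874) among them, but Cyp3a11, Cyp3a16, Cyp3a25 and Cyp3a44 had at most 19 counts in either humanized group, too few to show an effect. Of 18 NRF2 targets, 0 passed, with 2 unadjusted and 0 by DESeq2 (median 0.04, mean -0.07, camera adjusted p = 0.514 for a fall). Of 25 cholesterol synthesis genes, 0 passed, with 1 higher and 2 lower unadjusted and 0 by DESeq2 (camera adjusted p = 0.713). Gadd45b did not pass (0.33, adjusted p = 0.661, 2 of 4). Of 14 growth-arrest and p53 genes 1 fell (camera adjusted p = 0.577), as did 1 of 20 interferon genes (median 0.02, mean -0.05, camera adjusted p = 0.658 for a fall). Among 20 genes of the unfolded protein response the asparagine synthetase gene Asns fell, from 42.7 ± 12.4 to 5.94 ± 2.58 CPM (-2.86, adjusted p = 0.00907; list median 0.05, mean -0.05, camera adjusted p = 0.878 for a fall).

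Part of the clock genes changed in humanized liver. Of 18 clock genes, 7 rose and 2 fell (11 and 4 adjusted over the list alone), with a median log2 change of 0.79 (camera adjusted p = 0.000146, and adjusted p = 0.194 with an estimated correlation). The numbers were 3 and 1 without humanized vehicle replicates 1, 3 or 4, 7 and 4 without humanized TCPOBOP replicate 2, and 4 and 1 without humanized TCPOBOP replicate 3. Dbp, an output transcription factor of the clock (NM_016974, chromosome 7, 45705100 to 45710203), rose 16.1-fold, from 4.63 ± 1.12 to 74.7 ± 37.9 CPM (4.01 ± 0.55, adjusted p = 0.00132). Bhlhe41 (3.47, adjusted p = 0.00671) rose and the repressor gene Cry1 fell (-1.20, adjusted p = 0.00567). The rhythmic liver genes Rgs16 (3.62, adjusted p = 0.0019) and Serpina12 (4.52, adjusted p = 0.00132) rose as well.

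Some glucose-handling genes rose in humanized liver. Of 21 genes, Slc2a2, which had fallen in wild-type liver, Pfkfb3, Gys2 and Pygl rose (9 adjusted over the list alone, median 0.41, camera adjusted p = 0.000371, and adjusted p = 0.248 with an estimated correlation). Their number was 2 without humanized vehicle replicates 1, 3 or 4 or humanized TCPOBOP replicates 3 or 4, and 7 without wild-type vehicle replicate 2. Slc2a2, the main hepatic glucose transporter gene (NM_031197, chromosome 3, 28697903 to 28728361), rose 6.04-fold, from 32.6 ± 3.35 to 197 ± 103 CPM (2.59 ± 0.34, adjusted p = 0.00116). Pfkfb3, a regulator of glycolysis, rose by 2.35 (adjusted p = 0.0019). Of 35 fatty acid oxidation and PPAR alpha genes, 2 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0456, and adjusted p = 0.693 with an estimated correlation). It did not pass without humanized vehicle replicate 2 (0.191) or humanized TCPOBOP replicates 1 (0.078), 2 (0.0594) or 3 (0.26), and 4 and 5 genes rose without humanized TCPOBOP replicate 1 and wild-type vehicle replicate 2, against 0 without humanized vehicle replicate 2 or humanized TCPOBOP replicate 3. Of 27 lipogenesis genes, 2 rose and 1 fell (2 and 3 adjusted over the list alone, median -0.05, mean 0.02, camera adjusted p = 0.981 for a rise), and of 28 lipoprotein genes 2 rose by either adjustment (camera adjusted p = 0.577). Of 21 bile acid genes 1 rose (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0463, and adjusted p = 0.512 with an estimated correlation). That list did not pass without humanized vehicle replicates 1 (0.0879) or 4 (0.0755) or humanized TCPOBOP replicates 2 (0.119), 3 (0.276) or 4 (0.0574). Below the threshold stayed Ppara (1.11, adjusted p = 0.058, 3 of 4), Cyp7a1 (-1.32, adjusted p = 0.0632, 3 of 4), Srebf1 (0.31, adjusted p = 0.79), Pnpla3 (-0.65, adjusted p = 0.792) and Fasn (0.52, adjusted p = 0.561).

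Few sex-biased, zonal and stellate cell genes passed in humanized liver. Of 19 male-biased genes, Mup1, Mup12, Slco1a1 and Hsd3b5 rose (10 adjusted over the list alone, median 0.79, camera adjusted p = 1.22e-08, and adjusted p = 0.248 with an estimated correlation). Their number was 1, 2, 1 and 0 without humanized vehicle replicates 1, 2, 3 and 4, 1 without humanized TCPOBOP replicate 4, and 7 without humanized TCPOBOP replicate 1 or wild-type vehicle replicate 2. The steroid dehydrogenase gene Hsd3b5 rose by 3.26 (adjusted p = 0.0108, and 0.0566 without humanized vehicle replicate 4). Male-biased genes were lower in humanized than in wild-type vehicle livers (8 of 19), and over the list humanized TCPOBOP livers differed from wild-type vehicle livers by a median of 0.176, in a comparison chosen after the data were seen. Of 15 female-biased genes 1 fell (6 adjusted over the list alone, median -0.77, camera adjusted p = 0.00356, and adjusted p = 0.362 with an estimated correlation). Of 18 pericentral genes 1 rose (7 adjusted over the list alone, median 0.46, camera adjusted p = 0.000169, and adjusted p = 0.229 with an estimated correlation), and 5 rose without wild-type vehicle replicate 2. Of 18 periportal genes 1 rose and 1 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0575). This list passed without humanized vehicle replicate 1 (0.0102), humanized TCPOBOP replicate 3 (0.0167), wild-type vehicle replicates 2 (0.0279) or 3 (0.0429) or wild-type TCPOBOP replicate 4 (0.0336). Of 16 stellate cell markers, Ecm1, Colec11 and Hand2 fell (5 adjusted over the list alone, median -0.51, camera adjusted p = 5.94e-05, and adjusted p = 0.237 with an estimated correlation). Their number was 1 without humanized vehicle replicate 4 and 2 to 4 without any other 1 library. Ecm1 fell from 146 ± 14.0 to 67.6 ± 12.6 CPM (-1.11, adjusted p = 0.00394). The matrix genes Col5a2 (-3.18) and Loxl4 (-2.25), the activin antagonist gene Fst (-2.36) and the choline kinase gene Chka (-2.14) fell too. Chka had an adjusted p = 0.00861 in the fit of all groups and 0.0554 in the fit of the compared groups alone, the highest of its alternatives.

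The remaining lists in humanized liver rested on few genes. Of 26 acute phase genes Orm3 rose (2.78, adjusted p = 0.00567; 2 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.0463, and adjusted p = 0.737 with an estimated correlation). The list did not pass without humanized vehicle replicates 1 (0.214) or 3 (0.0754), humanized TCPOBOP replicates 1 (0.626) or 2 (0.149), wild-type vehicle replicate 2 (0.0753) or wild-type TCPOBOP replicate 2 (0.0508). Of 3 neutrophil markers 0 passed in edgeR, with 1 unadjusted and 1 by DESeq2 (camera adjusted p = 0.0331, and adjusted p = 0.362 with an estimated correlation). It did not pass without humanized vehicle replicate 3 (0.0513) or humanized TCPOBOP replicates 1 (0.128) or 3 (0.0523). Of 7 erythroid markers 0 passed, with 2 unadjusted and 0 by DESeq2 (camera adjusted p = 0.0169, and adjusted p = 0.482 with an estimated correlation), and the list did not pass without humanized TCPOBOP replicate 4 (0.105). Of 16 sinusoidal endothelial markers 0 passed, with 1 unadjusted and 0 by DESeq2. Their camera adjusted p was 0.363, and 0.00513 and 0.00939 without humanized TCPOBOP replicates 3 and 4. Of 16 Kupffer cell markers 1 fell (2 adjusted over the list alone, camera adjusted p = 0.524 for a rise, and 0.0393 without humanized TCPOBOP replicate 1). For 9 cholangiocyte markers the number was 0 in edgeR, with 1 higher and 2 lower unadjusted and 1 lower by DESeq2 (1 fell adjusted over the list alone, camera adjusted p = 0.363, and 0.0404 without humanized TCPOBOP replicate 2). Of 4 lymphocyte markers 1 fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.196), and of 4 adipocyte markers 1 rose (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.238). Of 2 pancreatic acinar markers 0 passed, with 1 unadjusted and 0 by DESeq2.

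The number of genes called in humanized liver depended on single libraries. Against 325 with all libraries, it was 86, 109 and 74 without humanized vehicle replicates 1, 3 and 4, and 157 and 160 without humanized TCPOBOP replicates 3 and 4. It was 960 without humanized TCPOBOP replicate 1 and 685 without wild-type vehicle replicate 2, and 216, 173 and 196 without wild-type TCPOBOP replicates 1, 3 and 4. At an unadjusted p under 0.05 there were 2310 genes, and 1285 genes, 9.95%, had no overlap between the groups, where chance gives 2.86%.

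Both responses were compared to ask whether the same genes moved in both strains. In the same direction, 50 genes were called in both, against 21.6 expected for independent sets. Of these, 37 rose in both, against 13.9 (Fisher's exact test, one-sided p = 2.47e-08), and 13 fell in both, against 7.7 (p = 0.0446, exact). In opposite directions, 30 genes fell in wild-type and rose in humanized liver, against 8.5 (p = 1.46e-09, exact), and 13 did the reverse, against 12.5 (p = 0.481, exact). Genes are not independent replicates and both lists come from 1 fit, so these p-values do not measure variation between mice. Cyp2b10 and Cyp1a2 rose in both, and Slc2a2 fell in wild-type and rose in humanized liver. The 50 genes became 16, 20 and 12 without humanized vehicle replicates 1, 3 and 4, and 111 without humanized TCPOBOP replicate 1. They became 29 and 26 without humanized TCPOBOP replicates 3 and 4, 93 without wild-type vehicle replicate 2, and 23 and 24 without wild-type TCPOBOP replicates 3 and 4. Across all 12913 genes, the 2 sets of log2 changes had a Pearson r of 0.065 and a Spearman rho of 0.073, and 53% had the same sign. These were 0.175, 0.109 and 58.8% among the 325 genes called in humanized and 0.033, 0.035 and 53.8% among the 1691 called in wild-type liver.

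The interaction asked which effects of TCPOBOP differed between the strains, as the effect in humanized minus that in wild-type mice. Induction was smaller in humanized liver for some conjugation and efflux genes (18 of 38), some CYP2 genes (5 of 14) and 22 of 37 cell-cycle genes. Some genes of fat oxidation, glucose handling and male bias were relatively higher. With an estimated correlation between genes, the fat oxidation and male-biased lists did not pass. The effect was higher in humanized liver for 449 genes and lower for 514, 963 in all, with 2740 at an unadjusted p under 0.05. All 43 genes called in opposite directions were among them. The number was 630 without humanized vehicle replicate 4, 1782 without humanized TCPOBOP replicate 1, 1705 without wild-type vehicle replicate 2, and 618 and 575 without wild-type TCPOBOP replicates 3 and 4.

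Of 38 conjugation and efflux genes, 18 had a lower effect in humanized liver (25 lower and 1 higher adjusted over the list alone, median -1.31, camera adjusted p = 4.68e-35, and adjusted p = 0.000593 with an estimated correlation). Gsta1 (-10.71 ± 0.78, adjusted p = 3.85e-07), Gstm3 (-6.91 ± 0.36, adjusted p = 3.48e-09) and Ces2a (-3.03) were among them. Of the 14 CYP2 genes, 5 were lower and Cyp2c38 was higher (7 and 1 adjusted over the list alone, median -0.96, camera adjusted p = 6.96e-06, and adjusted p = 0.0204 with an estimated correlation), with Cyp2b10 at -3.45 (adjusted p = 0.00141) and Cyp2c55 at -4.91 (adjusted p = 3.02e-06). Of 18 NRF2 targets 6 were lower (8 adjusted over the list alone, median -0.62, camera adjusted p = 1.35e-11, and adjusted p = 0.0204 with an estimated correlation), Srxn1 (-2.74) and Nqo1 (-2.48) among them. Of 37 cell-cycle genes, 22 were lower and Mcm10 was higher (31 and 1 adjusted over the list alone, median -2.57, camera adjusted p = 3.26e-28, and adjusted p = 0.0281 with an estimated correlation), with Mki67 at -3.16 (adjusted p = 0.000856) and Prc1 at -3.76. Of 14 growth-arrest and p53 genes 2 were lower, Myc (-2.37) and Cdkn1a (-2.91) (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0206, and adjusted p = 0.107 with an estimated correlation). Cyp3a11 (-2.39, adjusted p = 0.0869), Cyp3a13 (-1.19, adjusted p = 0.0525), Ccnd1 (-1.84, adjusted p = 0.0583), Fasn (-0.08, adjusted p = 0.966) and Cyp7a1 (-1.34, adjusted p = 0.12) did not pass. The Cyp3a list passed with 1 lower gene (3 adjusted over the list alone, camera adjusted p = 0.0106, and adjusted p = 0.206 with an estimated correlation), and not without wild-type vehicle replicate 2 (0.0509). As 4 of its 7 members had at most 19 counts in either humanized group, it does not show a different effect of TCPOBOP on them.

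Of 35 fatty acid oxidation genes, 13 had a higher effect in humanized liver (19 higher and 1 lower adjusted over the list alone, median 0.99, camera adjusted p = 1.29e-12, and adjusted p = 0.0583 with an estimated correlation). Their number was 8 without humanized vehicle replicate 4 or wild-type TCPOBOP replicates 3 or 4. Ppara (2.32 ± 0.43, adjusted p = 0.00262) was among them. Of 28 lipoprotein genes 4 were higher by either adjustment, Scarb1 (1.44) and Lrp1 (1.72) among them (median 0.71, camera adjusted p = 3.11e-05, and adjusted p = 0.0281 with an estimated correlation). Of 21 glucose-handling genes 6 were higher (9 adjusted over the list alone, median 0.78, camera adjusted p = 4.5e-08, and adjusted p = 0.0451 with an estimated correlation), and 10 without humanized TCPOBOP replicate 1. Slc2a2 differed by 4.12 ± 0.47 (adjusted p = 4.27e-05) and Pck1 by 2.04 ± 0.41 (adjusted p = 0.0046). Of 21 bile acid genes 3 were higher and 1 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.00302, and adjusted p = 0.217 with an estimated correlation), with 5 and 6 higher without humanized TCPOBOP replicate 1 and wild-type vehicle replicate 2. Of 19 male-biased genes 9 were higher (11 adjusted over the list alone, median 2.16, camera adjusted p = 1.71e-09, and adjusted p = 0.146 with an estimated correlation), Hsd3b5 (5.73, adjusted p = 0.000594) among them. Of 18 clock genes 5 were higher (11 higher and 1 lower adjusted over the list alone, median 0.89, camera adjusted p = 7.56e-05, and adjusted p = 0.0583 with an estimated correlation), led by Dbp (4.20, adjusted p = 0.00148). Their number was 3 without humanized vehicle replicate 3 or wild-type TCPOBOP replicate 4 and 8 without humanized TCPOBOP replicate 1. Pericentral genes, with 6 higher (8 adjusted over the list alone, camera adjusted p = 0.00724, and adjusted p = 0.211 with an estimated correlation), included Slc1a2 (2.01). Periportal genes, with 3 higher (4 adjusted over the list alone, camera adjusted p = 0.000452, and adjusted p = 0.251 with an estimated correlation), had 5 without humanized TCPOBOP replicate 1.

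The other lists that passed in the interaction rested on fewer genes. Of 5 aryl hydrocarbon receptor targets 2 were lower by either adjustment (camera adjusted p = 0.0313, and adjusted p = 0.146 with an estimated correlation). That list did not pass without humanized TCPOBOP replicate 1 (0.0998), humanized vehicle replicate 2 (0.0544) or wild-type vehicle replicate 2 (0.0798). Of 25 cholesterol synthesis genes 1 was lower (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00994, and adjusted p = 0.468 with an estimated correlation). It did not pass without humanized vehicle replicate 2 (0.0691) or wild-type TCPOBOP replicate 2 (0.0559), and 6 were lower without wild-type vehicle replicate 2. Of 26 acute phase genes 3 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00132, and adjusted p = 0.44 with an estimated correlation), with 5 higher without humanized TCPOBOP replicate 3 or wild-type vehicle replicate 4. Of 7 erythroid markers 0 passed in edgeR, with 4 unadjusted and 0 by DESeq2 (1 higher adjusted over the list alone, camera adjusted p = 0.00418, and adjusted p = 0.285 with an estimated correlation).

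The comparison of humanized with wild-type mice under vehicle gave the baseline of the strains. Apart from Nr1i3, Nr1i2 and Cyp3a genes, clock genes moved in both directions in livers of humanized vehicle mice. Lower there were some glucose-handling genes (6 of 21), some Kupffer cell markers (10 of 16) and some sinusoidal endothelial markers (7 of 16). With an estimated correlation between genes these 3 lists did not pass (adjusted p = 0.442, 0.512 and 0.512), nor did the other 9 lists called between the strains. Dbp was 11.4-fold lower and Nfil3 was higher. Past the threshold were 918 higher and 1156 lower genes, 2074 in all, and 996 differed at least 2-fold. At an unadjusted p under 0.05 there were 4444, and 3415 genes, 26.4%, had no overlap between the groups, where chance gives 2.86%. The number of calls was 621, 770 and 794 without humanized vehicle replicates 1, 3 and 4, 1291 without wild-type vehicle replicate 1 and 3425 without humanized TCPOBOP replicate 1, whose values enter through the shared estimate of spread.

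Of 18 clock genes, Arntl, Npas2, Cry1 and Nfil3 were higher and 6 were lower in humanized vehicle livers (4 and 10 adjusted over the list alone, median -0.64, camera adjusted p = 0.143). The numbers were 4 and 3 without humanized vehicle replicate 1 or wild-type vehicle replicate 1, 3 and 3 without humanized vehicle replicates 3 or 4, and camera gave 0.0178 without wild-type vehicle replicate 3. Nfil3 was at 24.3 ± 7.91 CPM in wild-type and 108 ± 21.9 CPM in humanized vehicle livers (2.14, adjusted p = 0.00196), and Dbp at 53.1 ± 32.0 and 4.63 ± 1.12 CPM (-3.51, adjusted p = 0.00131). Noct, a rhythmic deadenylase gene, was 11.4-fold higher (3.50, adjusted p = 1.43e-06), whereas Rgs16 (-3.84) and Serpina12 (-4.24) were lower. Of 21 glucose-handling genes 6 were lower (7 adjusted over the list alone, median -0.35, camera adjusted p = 0.00131, and adjusted p = 0.442 with an estimated correlation), led by Slc2a2 (-2.98, adjusted p = 0.000104) and Pfkfb3 (-2.50). Among 27 lipogenesis genes 3 were higher and 8 lower (3 and 12 adjusted over the list alone, camera adjusted p = 0.0268, and adjusted p = 0.69 with an estimated correlation). The number lower was 4 without humanized vehicle replicates 3 or 4, and camera gave 0.0518, 0.0563 and 0.143 without humanized vehicle replicate 3 and wild-type vehicle replicates 1 and 2. Fasn fell from 1499.5 ± 1076 to 384 ± 83.2 CPM (-1.96, adjusted p = 0.0103), and the pyruvate kinase gene Pklr was lower (-2.35, adjusted p = 0.000673). Cholesterol synthesis had 8 of 25 genes lower by either adjustment (camera adjusted p = 0.00131, and adjusted p = 0.595 with an estimated correlation). Their number was 0 without humanized vehicle replicate 1 or 3, 2 without humanized vehicle replicate 4, and 4 without wild-type vehicle replicate 3 or 4.

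**Figure D3:**
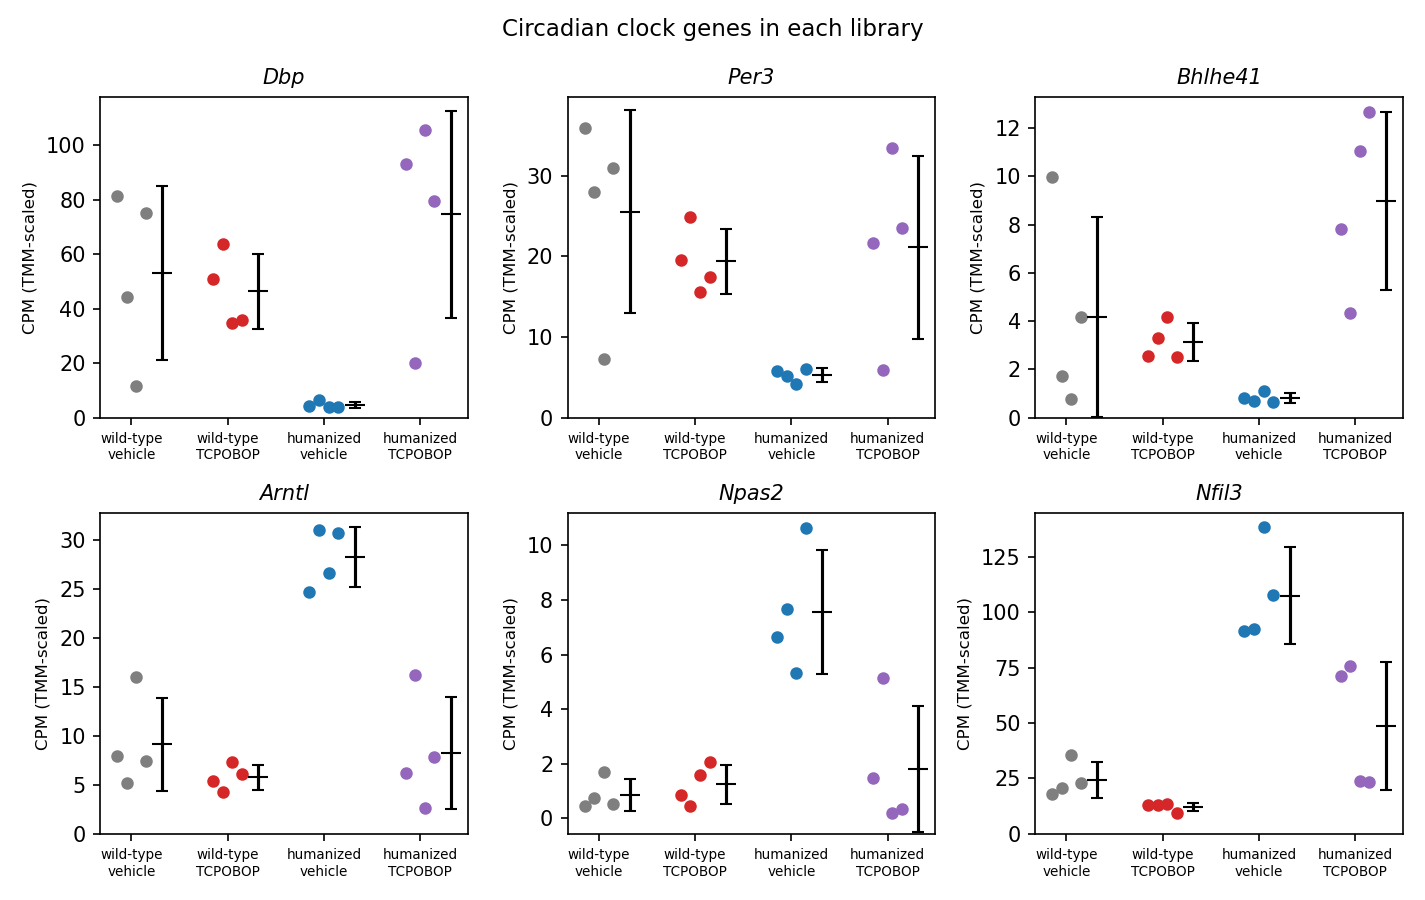
TMM-scaled CPM (vertical axes) of 6 clock genes in each library of the 4 groups (points), with mean and SD (bars, n = 4 mice). Nfil3 averages 108 CPM in humanized vehicle livers and 24.3 CPM in wild-type vehicle livers.

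Some drug-metabolism genes differed between the strains under vehicle. Of the 14 CYP2 genes 5 were lower and 1 higher (7 and 1 adjusted over the list alone, median -0.68, camera adjusted p = 0.0209, and adjusted p = 0.442 with an estimated correlation), Cyp2c50 (-1.99, adjusted p = 0.00383) and Cyp1a2 (-0.94, adjusted p = 0.0086) among them. Cyp2b10 was lower (-1.47, adjusted p = 0.0253, 3 of 4 libraries). Its adjusted p was 0.0514, 0.0513, 0.0711 and 0.0696 without humanized vehicle replicates 1, 2, 3 and 4, and 0.0903 without wild-type vehicle replicate 3. Of 7 Cyp3a genes 4 were lower and 1 higher (4 and 2 adjusted over the list alone, median -5.35, camera adjusted p = 3.87e-07, and adjusted p = 0.0859 with an estimated correlation). Of 38 conjugation genes 8 were higher and 1 lower (8 and 2 adjusted over the list alone, median -0.09, mean 0.16, camera adjusted p = 0.262 for a rise), with Gstm3 at 1.99 (adjusted p = 0.000175). The number higher was 4 and 5 without humanized vehicle replicates 1 and 4 and 5 without wild-type vehicle replicates 1 or 3. The number lower was 4 without humanized TCPOBOP replicate 1.

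Some sex-biased, bile acid, cell-cycle and acute phase genes differed between the strains as well. Of 19 male-biased genes 8 were lower and 1 higher (10 and 1 adjusted over the list alone, median -0.67, camera adjusted p = 0.0219, and adjusted p = 0.69 with an estimated correlation). The number lower was 3 without humanized vehicle replicates 1 or 4, and the list did not pass without humanized vehicle replicate 1 (0.0656) or wild-type vehicle replicates 3 (0.0821) or 4 (0.133). Of 21 bile acid genes 4 were lower and 1 higher by either adjustment (camera adjusted p = 0.0364, and adjusted p = 0.657 with an estimated correlation), with 7 lower without wild-type vehicle replicate 2. It did not pass without humanized vehicle replicates 1 (0.0623) or 4 (0.0645) or wild-type vehicle replicates 3 (0.102) or 4 (0.12). Of 37 cell-cycle genes 7 were lower (9 adjusted over the list alone, median -0.76, camera adjusted p = 0.0211, and adjusted p = 0.69 with an estimated correlation). Their number was 2 without any 1 of the humanized vehicle libraries, wild-type TCPOBOP replicate 3 or wild-type vehicle replicate 2, where camera gave 0.477. It was 3 without wild-type TCPOBOP replicate 4, 4 without wild-type TCPOBOP replicates 1 or 2 or wild-type vehicle replicate 1, 11 without humanized TCPOBOP replicate 1 and 12 without wild-type vehicle replicate 3. Of 26 acute phase genes 3 were higher (2 adjusted over the list alone, camera adjusted p = 0.0268, and adjusted p = 0.69 with an estimated correlation), and 5 without humanized TCPOBOP replicate 1. It did not pass without humanized vehicle replicates 2 (0.0951) or 4 (0.075) or wild-type vehicle replicate 4 (0.197).

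Several markers of Kupffer, sinusoidal endothelial and erythroid cells were lower in humanized vehicle livers. Of 16 Kupffer cell markers 10 were lower (11 adjusted over the list alone, median -1.24, camera adjusted p = 4.47e-06, and adjusted p = 0.512 with an estimated correlation), and 5 without humanized vehicle replicates 3 or 4. Clec4f was at 201 ± 14.5 and 97.7 ± 13.9 CPM (-1.04, adjusted p = 0.0031), and Folr2 (-1.86) and Csf1r (-1.92) were lower too. Of 16 sinusoidal endothelial markers 7 were lower (14 adjusted over the list alone, median -1.01, camera adjusted p = 3.48e-06, and adjusted p = 0.512 with an estimated correlation), Tek (-0.94) and Stab2 (-1.23) among them. Their number was 4, 2 and 3 without humanized vehicle replicates 1, 3 and 4, and 13, 11 and 12 without humanized TCPOBOP replicates 1, 2 and 3. Of 7 erythroid markers 6 were lower by either adjustment (camera adjusted p = 0.000237, and adjusted p = 0.442 with an estimated correlation), and 1, 1 and 2 without humanized vehicle replicates 1, 3 and 4. Markers of other cells did not pass as lists. Of 16 stellate cell markers 3 were lower and 1 higher (7 and 1 adjusted over the list alone, camera adjusted p = 0.125, and 0.0483 without wild-type vehicle replicate 3), with 5 lower without humanized TCPOBOP replicate 1. Of 9 cholangiocyte markers 1 was higher by either adjustment (median 0.32, camera adjusted p = 0.448). Of 3 neutrophil markers 0 passed in edgeR, with 2 higher unadjusted, by DESeq2 and adjusted over the list alone (median 1.155, camera adjusted p = 0.133, and 0.0206 without wild-type vehicle replicate 3, where 2 were higher). Of 4 lymphocyte markers 1 was lower (2 higher and 1 lower adjusted over the list alone, median 0.63, camera adjusted p = 0.827 for a rise). For 4 adipocyte markers the number was 0 by edgeR, unadjusted and by DESeq2 (camera adjusted p = 0.608).

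The strain differences ran along transcript length. Of 840 genes with transcripts up to 1000 bases, 15.1% were higher and 3.7% lower in humanized vehicle livers, and of 2187 genes with transcripts over 5000 bases 4.2% were higher and 15.8% lower. Across genes, the strain difference and transcript length had a Spearman rho of -0.353, against -0.035 and 0.104 for the effects of TCPOBOP in wild-type and humanized mice. With that trend removed, 11 Kupffer cell, 7 endothelial and 6 erythroid markers were lower. Humanized TCPOBOP replicates 1 and 2 shared the trend of the humanized vehicle libraries, and replicates 3 and 4 did not.

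**Figure D4:**
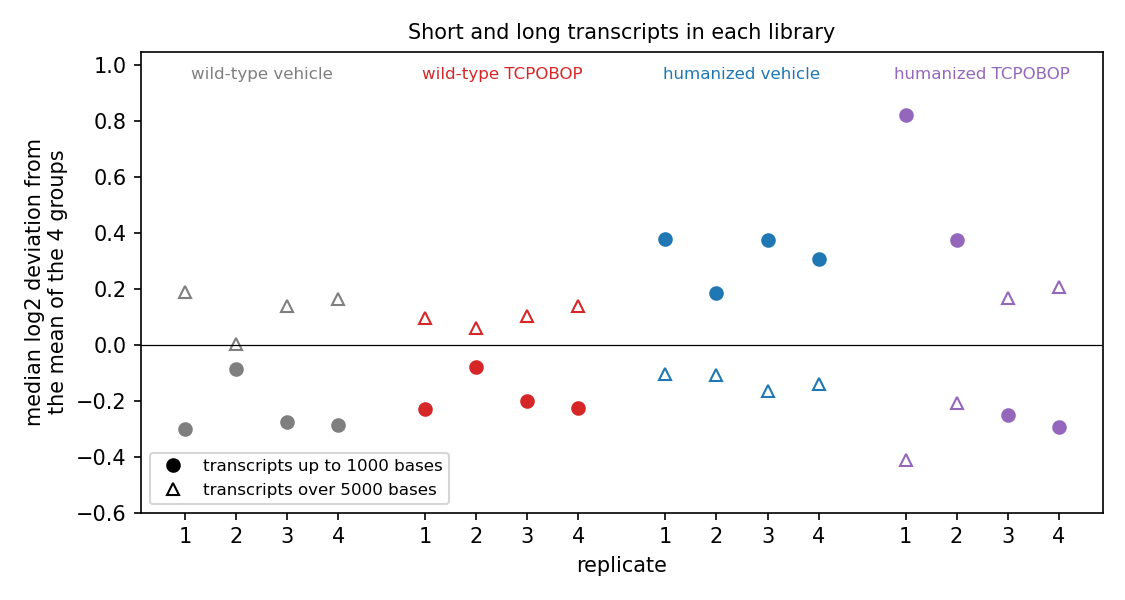
Median log2 deviation of each library from the mean of the 4 groups (vertical axis) for transcripts up to 1000 bases (circles) and over 5000 bases (triangles), by replicate within each group (horizontal axis). Humanized TCPOBOP replicate 1 is at 0.824 for short and -0.412 for long transcripts.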

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

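The tests of the clock genes, of the shared length trend, of exchanged labels and of carry-over were chosen only after the result was seen; the splits of the libraries and the tests of length or GC bias in 1 library alone were not, although leaving humanized TCPOBOP replicate 1 out of the references was a later choice.

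The effect of TCPOBOP differed between the strains for 963 genes and 18 lists by the interaction test. Of 100 splits drawn at random, 3 gave as many genes, the real one included, with 1304 the highest of the others. The 95 splits that mixed the strains among the TCPOBOP libraries gave at most 11 genes and the 5 that did not gave 402 to 1304, so the share follows this mixing, and the splits do not show whether chance is excluded. The largest differences on the log2 scale, humanized minus wild-type, were Hsd3b5 (5.73), Cyp2c69 (5.71), Obp2a (5.59), Cyp4a10 (5.37), Mup12 (5.36), Isyna1 (5.33), Serpina12 (5.22), Mup1 (4.99), Aqp4 (4.84) and Ugt2b38 (4.61). In the other direction they were Gsta1 (-10.7), Sult1e1 (-10.22), Meig1 (-8.89), Ppp1r42 (-8.43), Nebl (-7.25), Gprc5a (-7.04), Gstm3 (-6.91), Tmprss7 (-6.45), Sytl5 (-6.43) and Akr1b7 (-6.16). Nebl lost the call without humanized vehicle replicate 1 (adjusted p = 0.97). Several of these genes had few counts in 1 group, so their fitted sizes depend on the prior count. Among named genes called in opposite directions, differences were 1.76 (Fabp2), -3.38 (Gsta2), -4.04 (Noct), 4.12 (Slc2a2) and 3.86 (Slco1a1).

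Clock genes set the humanized vehicle livers apart from most libraries of the other 3 groups. Wild-type vehicle replicate 3 lay towards them, with Dbp at 11.64 CPM against 44.43 to 81.29 CPM in the other 3 and Bhlhe41 at 0.751 CPM, within their range of 0.6261 to 1.121 CPM, and humanized TCPOBOP replicate 2 had Per3 at 5.859 CPM, within 4.205 to 6.053 CPM. Of the 10 clock genes called between the strains under vehicle, 9 kept the call with the length trend removed, which argues against that trend as the whole cause. Between humanized TCPOBOP and wild-type vehicle livers 0 of the 10 were called in edgeR (3 at an unadjusted p under 0.05, 1 without humanized TCPOBOP replicate 3 or without replicate 4) and 0 in DESeq2. Over all 18 clock genes, a list written before the data were examined, the median size of the log2 differences in that comparison was 0.3, against 0.89 under vehicle, which argues against a fixed effect of the humanized genotype alone. TCPOBOP in humanized mice moved 7 of the 10 the opposite way, but these comparisons share the humanized vehicle libraries, which favours opposite signs. With 2 of these libraries in 1 comparison and the other 2 in the other, 15 to 17 of the 18 genes had opposite signs in the 6 ways of parting them, as did 65.4 to 71.7% of all genes, where 50% would be expected without a shift of the group. Another time of collection or feeding state of the humanized vehicle mice and an effect of TCPOBOP on the clock in humanized liver cannot be told apart, since time of day and feeding are not given in the sources used here and the state would coincide with the group.

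Humanized TCPOBOP replicate 1 stood apart from its group. Its deviation from the other 3 libraries had a Spearman rho across genes of -0.439 with transcript length and 0.138 with GC content. Wild-type vehicle replicate 2 reached 0.656 with GC content, which argues against a GC bias of humanized TCPOBOP replicate 1 alone. For length, replicates 2 and 4 of its group were at -0.325 and 0.473 with replicate 1 among their references, and at -0.471 and 0.403 without it. These references differ from those of replicate 1, so the values do not show whether a length bias was in replicate 1 alone. In replicate 2 the median deviation of transcripts under 1000 bases was 0.262, or 0.661 with replicate 1 left out of the references. It was larger in replicate 1, at 0.877. Against the mean of the 4 groups its rho with length was -0.423, beside -0.37 for replicate 2 and -0.211 to -0.294 for the humanized vehicle libraries, so a candidate explanation is a length trend shared by 6 of the 8 humanized libraries, technical or biological. An exchange of labels with humanized vehicle replicate 2 was tested on genes called without both libraries, since the split that exchanges them called 575 genes, against 325. Of all 1117 such genes, 269 lay nearer their own group in both libraries and 287 on the exchanged side in both, which leaves an exchange open. Of 72 such members of the 30 lists, 40 and 6 did. Of 16 in the CYP2 and clock lists, 12 and 0 did, but these 2 lists were picked, and the cut-offs of the test set, after the result for all genes was seen. An earlier test on 3 chosen genes is not used. Of the 2074 genes called between strains under vehicle, 1574 were called the same way with the length trend removed, so the trend is not the whole cause of that difference.

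CAR targets were higher in humanized TCPOBOP than in humanized vehicle livers. Carry-over of RNA from wild-type TCPOBOP livers would need a share of 2.74% to give the Cyp2b10 level, and Cyp3a25 and Cyp3a11, the lost genes for which it would bring 10 CPM or more, a limit set after the result was seen, reached at most 0.49% of that level, which argues against it. Cyp3a59, for which it would bring 2.49 CPM, reached 38.3% on average and at most 73.9%, but was at 0.955 CPM in humanized TCPOBOP against 1.79 CPM in humanized vehicle livers. Of the 5 called members of the CYP2 list, 0 were higher in edgeR in humanized TCPOBOP than in wild-type vehicle livers (2 at an unadjusted p under 0.05, and 1, Cyp2c55, in DESeq2), with Cyp2b10 at 1.12 (adjusted p = 0.144), Cyp2c55 at 0.93 (adjusted p = 0.111), Cyp1a2 at 0.16 (adjusted p = 0.666), Cyp1a1 at -0.23 (adjusted p = 0.611) and Cyp2c50 at -0.58 (adjusted p = 0.345). An effect of TCPOBOP through the human receptors and a clock or feeding state of the humanized vehicle livers cannot be told apart for these 5 genes, because the state would coincide with the vehicle group.

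Splits of the libraries tested whether other groupings call as many genes. In wild-type mice 1 of 35 splits, the real one, gave 1691 genes, with 112 the highest of the others. Between the strains under vehicle 1 of 35 gave 2074, with 7 the highest of the others. Both shares were 2.9%, the smallest that 35 splits can give, which argues against chance without excluding it. The splits cannot separate treatment or strain from another cause that coincides with the groups. In humanized mice 2 of 35 splits gave as many as the 325 genes, with 575 for the split that exchanges humanized TCPOBOP replicate 1 and humanized vehicle replicate 2, so chance is not excluded for that number.

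Single libraries stood far from the other 3 of their group in 51 of 666 groups of values tested, or 7.7%. Chance would flag about 1 in 20 groups of normally distributed values, or 33.3. A group with counts in only 1 library is always flagged, such as Krt4 in humanized vehicle, Cyp3a57 and Meig1 in wild-type vehicle livers. The share therefore does not show an excess over chance. In 40 of them the library was the highest, and wild-type vehicle replicate 2 had the most, with 10. Values are CPM unless a unit is given, and the library is the highest of its group unless called low. Humanized TCPOBOP replicate 1 had Mt2 at 2020, Tmprss7 at 0.886 and Prc1 low at 0.591, replicate 2 had Ecm1 low at 48.8, and replicate 4 had Nebl at 0.119 and Pck1 low at 2690. Humanized TCPOBOP replicate 3 had Cyp2b10 at 201, Cyp7a1 at 102, Nipal1 at 2.66, Ppp1r42 at 0.102, Rgs16 at 394 and Saa4 low at 586. Humanized vehicle replicate 1 had Ccnb1 at 0.104, Cyp1a2 at 429, Cyp2b10 at 23.1, Gsta1 at 3.21, Meg3 at 19 and Nebl at 0.311. Humanized vehicle replicate 2 had Krt4 at 0.116 and Slc10a1 at 274, and replicate 3 had Pnpla3 low at 2.8 and Rsad2 low at 11.9. Wild-type TCPOBOP replicate 1 had Aurka low at 8.43 and Myc low at 29.3, replicate 3 had Abcg5 low at 34.2, and replicate 4 had Trib3 at 50.6. Wild-type TCPOBOP replicate 2 had Fads1 at 1430, Por at 2450, Tm7sf2 at 291 and a low share of Mup counts, 0.438%. Wild-type vehicle replicate 1 had Cyp2c38 at 38.7, Meig1 at 0.147, Ppp1r42 at 0.88 and a low total count over all accessions of 11.83 M. Wild-type vehicle replicate 2 had Ccnb1 at 0.951, Ehhadh at 2040, Kif20a at 4.38, Krt4 at 51.4, Mvk at 52.8, Prc1 at 2.47, Ptgds at 45.5, Slc34a2 at 74 and Stab2 at 199. Wild-type vehicle replicate 3 had Cyp3a57 at 0.0939 and Tek at 18, and replicate 4 had Acot1 at 9.73, Acss3 at 13.2, Cyp4a10 at 198, Gys2 at 216 and Sult1e1 at 0.0909. No explanation of these single values was tested.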

How the results depend on the processing

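The sum of isoforms, the thinned libraries, the fits without 2 libraries and the removal of length or length and GC trends were chosen after seeing the data; the other alternatives were planned. No named gene that was called in the main fit or in an alternative had the opposite direction in that alternative. Changes of sign in genes called in neither were not counted. The interaction has no fit of the compared groups alone. Lists were not tested with the DESeq2 Wald test, the fits of the compared groups alone or a 2-fold minimum, and the correlation has no value with a 2-fold minimum.

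Calls in wild-type liver stayed within 1.5 times 1691 under each alternative but 3. They were 990 with a 2-fold minimum and 3046 without humanized TCPOBOP replicate 1 and wild-type vehicle replicate 2, of which 1636 were among the 1691. They ranged from 1068, without wild-type TCPOBOP replicate 4, to 2190 when 1 library was left out. Between the strains under vehicle the same settings gave 996 and 4505 (2000 of the 2074 among them), and single libraries gave 621 (without humanized vehicle replicate 1) to 3425 (without humanized TCPOBOP replicate 1). With thinned libraries the counts were 1487, 221, 839 and 1923 in wild-type liver, humanized liver, the interaction and between strains, so the difference in number between the strains was also there with equal total counts.

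Calls in humanized liver moved most. Against 325, they were 771 with the DESeq2 Wald test (322 of the 325 among them), 769 with length and GC trends removed (318), 182 in the fit of the compared groups alone (143) and 2137 without the 2 libraries (all 325). With the replicate number as a block they were 209 (197), and calls in wild-type liver were 1692. After removal of group means, the 24 pairs of libraries with the same number in different groups had a median correlation of 0.002, against 0.003 for the other 72, and 4 of 16 libraries correlated best with their own number. Between wild-type vehicle and TCPOBOP the values for replicates 1 to 4 were 0.1, 0.581, 0.218 and 0.176, and both replicates 2 shared a trend with GC content (rho 0.656 and 0.638). Replicate 1 did not exceed 0.1, the limit set for every pair, and no label gives a shared litter or batch, so the main fit has no block. Single libraries left out gave 74 to 960 calls in humanized liver. Leaving out libraries removes both animals and their spread, and the cause of the other changes was not tested. Of 57 named genes called in humanized liver 20 kept the call without any 1 library, against 76 of 89 in wild-type liver.

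The interaction gave 1474 genes with the DESeq2 Wald test, which moved the median of all genes by 0.1096 on the log2 scale. It gave 1702 with length and GC trends removed, 3140 without the 2 libraries, and 575 to 1782 without 1 library. Genes called in both strains in the same direction, 50, became 123, 134 and 223 under these settings, 25 in the fits of the compared groups alone, 29 with a 2-fold minimum, and 12 to 111 without 1 library. The correlation across genes was -0.049 without the 2 libraries and -0.015 to 0.1 without 1 library, against 0.065, and the cause was not tested.

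With an estimated correlation, 6 of the 14 lists called in wild-type liver, 1 of 13 in humanized liver, 6 of 18 in the interaction and 0 of 12 between strains (2 at an unadjusted p under 0.05) passed. Leaving out 1 library gave 13 to 17, 10 to 14, 16 to 20 and 9 to 13 lists. Of the lists called, 10, 7, 15 and 7 passed in each of the 16 fits. The groups of 4 mice limit a 2-fold change to being found in about 1 of 2 genes in simulated data.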

Other observations

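All values in this part come from comparisons chosen after the data were seen. Humanized TCPOBOP and wild-type vehicle livers, a comparison the design did not name, differed for 66 genes, 26 higher and 40 lower, with 2774 at an unadjusted p under 0.05. The number was 26 and 23 without humanized TCPOBOP replicates 1 and 2, and 905 and 631 without replicates 3 and 4. It was 33, 44, 112 and 90 without wild-type vehicle replicates 1 to 4. Of the 325 genes called with TCPOBOP in humanized liver, 15 were called in this comparison, against 66 of all 12913 genes tested. At an unadjusted p under 0.05 there were 116 of the 325, against 2774 of all genes. Both comparisons share the humanized TCPOBOP libraries, which favours a larger share among the 325.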
